A study of Homo sapiens with 12 samples.

How the data were processed

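RNA was measured by sequencing in 12 human adipose tissue biopsies, 6 of subacromial fat (the fat beside the rotator cuff tendons under the shoulder blade's acromion, labelled RCA) and 6 of subcutaneous fat (labelled SQ). Each RCA library shares an identifier with 1 SQ library, and the 6 matched identifiers are called pairs 1 to 6 here. The labels do not say that the libraries of a pair come from 1 donor, nor that the libraries of a group come from separate donors, so the p-values measure the spread between these libraries. The study included torn and intact cuffs, but the labels used here do not say which library came from which, and that contrast was not analysed here.

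Total RNA was extracted with an RNeasy Mini kit, per the labels' protocols, which also name STAR 2.7.9a1 and Ensembl release 101. The submitters' processing notes name genome build GRCh38. The deposited values are whole-number read counts per gene, not normalized, for 60671 Ensembl gene identifiers. The counting program, its strand setting and any read filter are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies such as C4A and C4B may therefore have been split or lost, and values of such genes are uncertain. Symbols were found for 60647 identifiers. Biotypes and coordinates come from GENCODE 29 (GRCh38, the same build in an older annotation release), which holds 58453 of them. No read was counted for 11957 genes.

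The libraries held 20296871 to 32086480 counts. No 2 libraries agreed within sampling noise, so none was treated as a repeat of another. A check for mixed-up samples found that the 2 libraries of 1 of the 6 pairs did not match each other, and all pairs were kept in the main comparison.

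Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3; minimum count 10, minimum total count 15), which left 24929 genes. RCA was compared with SQ by edgeR's quasi-likelihood F-test with TMM factors, robust dispersion estimates and no block for the pair. Every adjusted p of a gene comes from that test with the Benjamini-Hochberg method over all genes tested, unless another test is named, and the threshold was 0.05. Fold changes are log2, RCA minus SQ, and their standard error (SE) is the size of the fold change divided by the square root of F. CPM values (counts scaled to library size) use the TMM-scaled library sizes, and log2 CPM has a prior count of 2. The steps were tested on simulated data for this comparison, with 24374 genes and 200 of them changed: of 100 genes simulated at an absolute log2 fold change of 1, 58% were recovered, and of 100 at 2, 94%. Of 163 calls, 11 were false. The changed genes were drawn from those with a log2 mean CPM of at least 1. Genes were simulated independently, with no pair effect and no library that stood apart, so these rates may not hold for the real data.

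30 gene lists with 614 members, 549 of them measured after filtering, were fixed before the data were examined and tested with camera in limma 3.58.1 (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists). Camera with an estimated correlation, and fry, were run beside it. Library composition was compared by exact two-sided permutation tests over all 924 assignments of the libraries (scipy 1.17.1).

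Named genes follow a rule set before the data were examined. It takes the 10 highest and 10 lowest fold changes among protein-coding genes past the threshold with a mean log2 CPM of at least 1 and the same direction in all 6 pairs. It adds the 2 members with the smallest p of each list that passed camera or had at least 3 members past the threshold, and 12 genes named in any case. Genes outside the rule are marked as chosen after their values were seen. Alternatives were the pair as a block, RLE and upper-quartile factors, no count filter or a stricter one, omission of mitochondrially encoded and haemoglobin genes, limma voom with sample weights or with duplicate correlation, DESeq2 1.42.0, each library left out in turn, other thresholds and a skeletal muscle covariate. An adipocyte covariate and the omission of libraries that stood apart or did not match were added after seeing the data.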

Results

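The series holds gene counts of 12 adipose biopsies from the human shoulder region, 6 of subacromial fat (RCA) and 6 of subcutaneous fat (SQ). The depth was 23964128 ± 4320531 counts in RCA and 24133845 ± 2687376 in SQ (SD, n = 6 each), and it ranged from 20296871 to 32086480. The comparison asks how fat next to the rotator cuff differs in gene expression from fat under the skin.

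Genes of the fat cell and of fatty acid synthesis were lower in RCA, and genes of synovial lining and matrix were higher, by camera with a preset correlation between genes; with an estimated correlation, fatty acid synthesis passed (adjusted p = 0.0128) and the other 3 lists did not (0.453, 0.743 and 0.743). With the mature adipocyte mean as a covariate, chosen after seeing the data, the medians of the synovial and matrix lists turned to -0.70 and -0.69, and the matrix list was called lower. Of 24929 genes tested, 885 were higher and 1516 lower in RCA at an adjusted p below 0.05 in edgeR's quasi-likelihood test. Among these, 421 of the higher and 447 of the lower genes changed by at least 1 on the log2 scale. 1820 of the 2401 genes (75.8%) had the same direction in all 6 pairs. The count was 4505 without the RCA library of pair 1, 1203, 1332 and 1313 without that of pairs 2, 3 and 4, and 1350, 1421 and 1471 without the SQ library of pairs 2, 3 and 5. It was 3817 with DESeq2 and, in fits chosen after seeing the data, 846 without the pair whose libraries did not match each other, 4202 without the RCA libraries of pairs 1 and 6, and 53 with the mature adipocyte mean as a covariate. With upper-quartile factors the split was 1118 higher and 1248 lower.

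**Figure D1:**
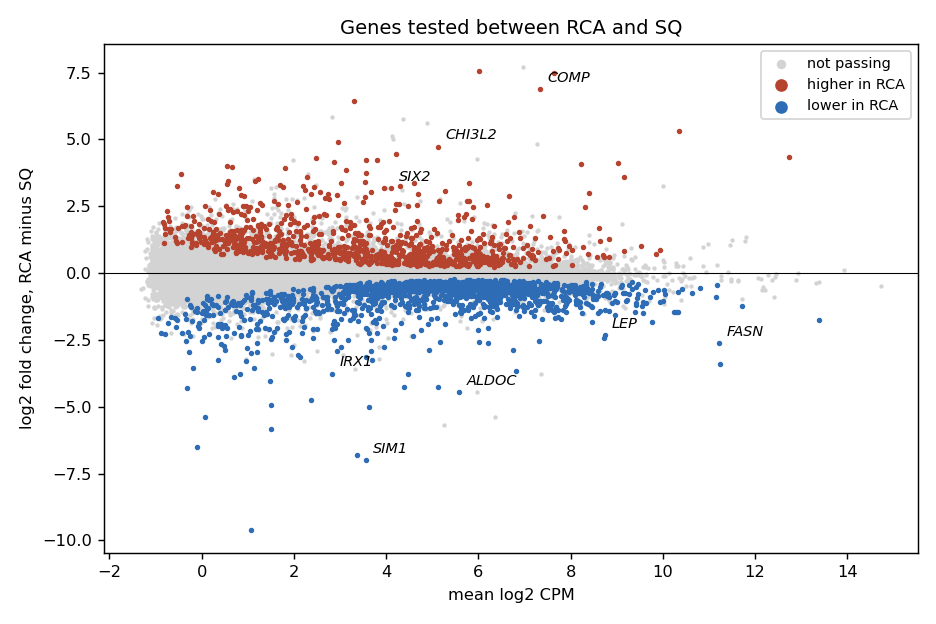
Log2 fold change (RCA minus SQ) against mean log2 CPM for the genes tested. Red points are the genes higher and blue points the genes lower in RCA at an adjusted p below 0.05, and grey points did not pass.

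Among the genes named for a high fold change in 1 direction in all 6 pairs, COMP had the highest (ENSG00000105664, GRCh38 chromosome 19, 18782773 to 18791314); it encodes a cartilage and tendon matrix protein. COMP was at 322 ± 412 CPM in RCA and 2.70 ± 2.88 CPM in SQ (SD, n = 6), a log2 fold change of 6.90 (SE 1.36, adjusted p = 0.0116, edgeR; 0.0783 in limma voom with duplicate correlation). PLA2G2A, a secreted phospholipase, rose by 4.12 (SE 0.77, adjusted p = 0.00948), with 995 ± 921 CPM in RCA and 57.0 ± 22.2 CPM in SQ. CHI3L2 rose by 4.73, SHISAL1 by 4.25, and PTN, which encodes the growth factor pleiotrophin, by 2.97. The transcription factor genes SIX2 (chromosome 2, 45005161 to 45009430) and SIM2 rose by 3.20 (SE 0.41, adjusted p = 0.00131) and 3.23 (SE 0.40, adjusted p = 0.000997). SIX2 stood at 31.0 ± 14.01 CPM in RCA and 3.39 ± 1.14 CPM in SQ. The complement genes C4B and C4A rose by 3.39 and 2.95, and as near-identical neighbours on chromosome 6 their separate values are uncertain. These 9 genes were higher in RCA in 6 of 6 pairs, which the rule for naming them required. The call was lost for CHI3L2 in 8 and for PTN in 4 of the 12 fits that left out 1 library, with adjusted p up to 0.0744 and 0.0586. With the pair as a block, neither PLA2G2A (adjusted p = 0.0526) nor CHI3L2 (0.0596) passed.

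Of the genes named here, SIM1 had the lowest fold change (ENSG00000112246, chromosome 6, 100385015 to 100464929). This transcription factor gene was at 0.155 ± 0.248 CPM in RCA and 23.2 ± 14.8 CPM in SQ. Its log2 fold change was -6.99 (SE 0.82, adjusted p = 0.00103, edgeR). DEFB132, a defensin gene, was at -6.80 and AADAC, which encodes an esterase, at -5.82. The cell adhesion gene NRCAM was at -5.01. ALDOC (ENSG00000109107, chromosome 17, 28573115 to 28577264), an aldolase of glycolysis, was at 4.17 ± 1.24 CPM in RCA and 91.5 ± 35.0 CPM in SQ, with a log2 fold change of -4.46 (SE 0.29, adjusted p = 1.02e-05). PCLO was at -4.27, SPX, which encodes the peptide spexin, at -4.24, ANKRD30A at -4.03, GALNT13 at -3.79 and IRX1 at -3.76. All 10 were lower in RCA in 6 of 6 pairs, which the rule for naming them required. SPX lost its call in 2 and GALNT13 in 7 of the 12 fits without 1 library, with adjusted p up to 0.0528 and 0.0904. Their fold changes were -2.71 without the SQ library of pair 5 (SPX) and -1.74 without that of pair 1 (GALNT13). NRCAM did not pass in limma voom with duplicate correlation (adjusted p = 0.0538), nor did GALNT13 there (0.0835) or with sample weights (0.0820).

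Fat cell genes fell together. Of the 30 measured members of the mature adipocyte list, 15 fell and none rose (23 fell when adjusted over the list alone), and the median log2 fold change was -1.17 (camera adjusted p = 7.88e-23, adjusted p = 0.453 with an estimated correlation). DGAT2, which catalyses the last step of triglyceride synthesis, was at 134 ± 40.1 CPM in RCA and 717 ± 277 CPM in SQ, a log2 fold change of -2.42 (SE 0.27, adjusted p = 0.000646, edgeR). PLIN4, a lipid droplet coat gene, fell by 1.76 (SE 0.20, adjusted p = 0.000705) from 16567 ± 3478 CPM in SQ to 4901 ± 1262 CPM in RCA. LEP, the gene of the fat hormone leptin, fell by 2.32 (SE 0.56, adjusted p = 0.0245), and its call was lost in 3 of the 12 fits without 1 library (adjusted p up to 0.0586). ADIPOQ, the gene of adiponectin, did not pass, at -0.83 (SE 0.25, adjusted p = 0.0545). It passed without the RCA library of pair 1 (adjusted p = 0.00170), in DESeq2 (0.0156) and with the pair as a block. The RCA library of pair 1 had a mean log2 CPM of 8.90 over the list, within the SQ range of 8.77 to 9.62. The other 5 RCA libraries ranged from 7.23 to 7.93.

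Fatty acid synthesis genes were lower as well. Of 18 measured members, 12 fell and none rose (15 fell when adjusted over the list alone), with a median of -1.04 (camera adjusted p = 8.12e-17). This was the 1 list of 30 that also passed with an estimated correlation (adjusted p = 0.0128). FASN, fatty acid synthase (chromosome 17, 82078333 to 82098332), was at 669 ± 341 CPM in RCA and 4123 ± 1664 CPM in SQ, a log2 fold change of -2.62 (SE 0.34, adjusted p = 0.00129, edgeR). ELOVL5, a fatty acid elongase gene, and ME1, the gene of cytosolic malic enzyme, which supplies NADPH, fell by 1.67 and 1.36. Of 26 nuclear genes of the mitochondrial respiratory chain, 13 fell and none rose (20 fell when adjusted over the list alone), with a median of -0.43 (camera adjusted p = 7.75e-10, adjusted p = 0.518 with an estimated correlation). NDUFB5 of complex I fell by 0.68 and ATP5F1C of ATP synthase by 0.52. The 13 mitochondrially encoded genes held no call at a median of -0.26 (camera adjusted p = 0.103). In the thermogenic or beige fat list, 1 of 19 members rose and 2 fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.596). EBF2, a transcription factor gene of brown and beige fat, rose by 0.83 and lost its call in 7 of 12 fits without 1 library (adjusted p up to 0.0679), and HSPB7, a small heat shock protein gene, fell by 1.84. UCP1, the uncoupling protein of thermogenic fat, failed the count filter with 87 counts in all RCA and 120 in all SQ libraries. In the fit without a count filter it was at -0.62 (SE 0.89, adjusted p = 0.760).

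**Figure D2:**
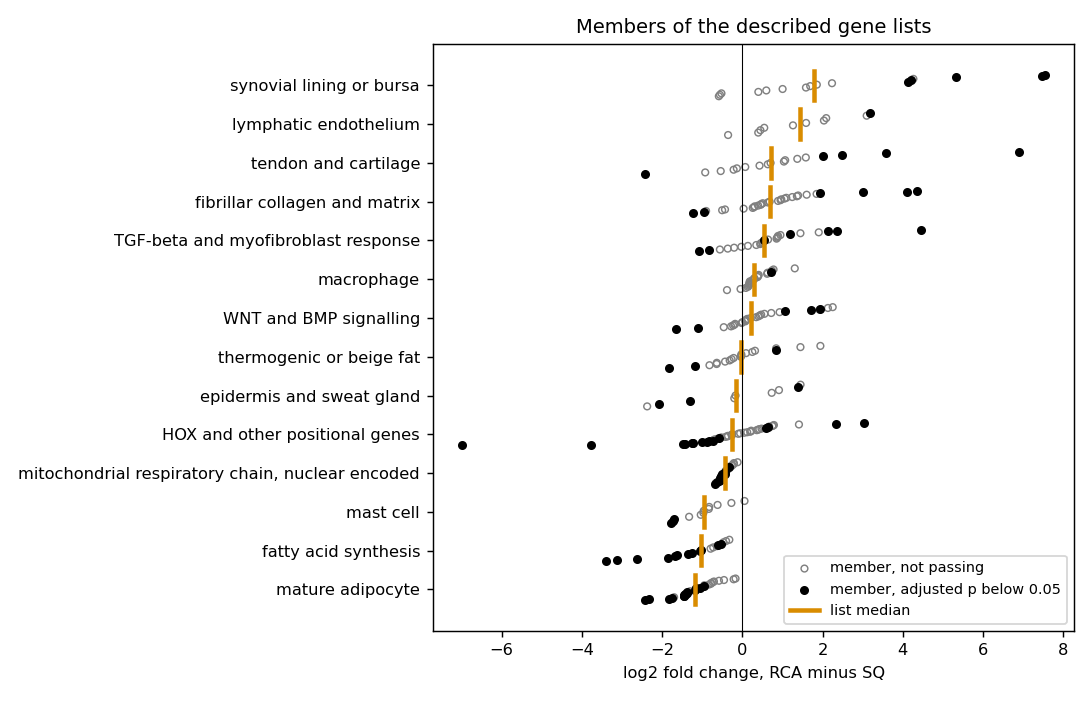
Log2 fold change (RCA minus SQ) of each measured member of the 14 lists described, 1 point per gene, with the list median as an orange bar. Filled points passed an adjusted p of 0.05; the mature adipocyte median is -1.17 and the synovial lining median is 1.77.

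Genes of the synovial lining, the tissue that coats joints and bursae, were higher in RCA. Of 16 measured members, 5 rose and none fell (10 rose when adjusted over the list alone), with a median of 1.77 (camera adjusted p = 0.00485, adjusted p = 0.743 with an estimated correlation; 0.0502 in camera without the RCA library of pair 4, where the median was 0.99). With the adipocyte covariate the median was -0.70 (camera adjusted p = 0.161), and -0.67 with it and without the RCA library of pair 1 (0.299). CRTAC1, a cartilage protein gene, was at 398 ± 578 CPM in RCA and 2.24 ± 1.4995 CPM in SQ, a log2 fold change of 7.47 (SE 1.596, adjusted p = 0.0163, edgeR), and was higher in 5 of 6 pairs. It did not pass in limma voom with sample weights (adjusted p = 0.0876) or with duplicate correlation (0.191). The RCA libraries of pairs 2 and 4 had the highest means over this list, 6.52 and 7.54 log2 CPM, against 2.77 to 4.64 in the other RCA libraries. Of 17 tendon and cartilage genes, 4 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.172). COMP was among those that rose. TNMD, a tendon gene that fat also expresses, fell by 2.43 (SE 0.40, adjusted p = 0.00504).

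Matrix and TGF-beta genes moved in both directions. Of 29 fibrillar collagen and matrix genes, 4 rose and 2 fell (12 and 2 when adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.00533, adjusted p = 0.743 with an estimated correlation). This call was lost without the RCA library of pair 2 (adjusted p = 0.0540) and without the SQ library of pair 5 (0.0632). With the adipocyte covariate the list was called lower at a median of -0.69 (camera adjusted p = 2.97e-08), and at -0.45 with it and without the RCA library of pair 1 (0.0298). SPARC, a collagen-binding matrix protein gene, fell by 1.24 (SE 0.16, adjusted p = 0.00120, edgeR) and PLOD2, a collagen lysyl hydroxylase gene, by 0.96. COL1A1 was at 1.05 (SE 0.67, adjusted p = 0.341; 1.77 without the SQ library of pair 1) and COL3A1 at 1.36 (SE 0.46, adjusted p = 0.0782), and neither passed; COL3A1 did without the RCA library of pair 1 (adjusted p = 0.00409) and in DESeq2 (0.0127). FN1, fibronectin, chosen after its value was seen, rose by 4.36 (SE 0.99, adjusted p = 0.0203) to 12993 ± 16915 CPM. Of 25 TGF-beta and myofibroblast response genes, 5 rose and 2 fell (11 and 2 when adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.00242, adjusted p = 0.518 with an estimated correlation). CCN2, a connective tissue growth factor gene induced by TGF-beta, rose by 2.13 (SE 0.33, adjusted p = 0.00343), and PMEPA1, also induced by TGF-beta, fell by 1.07 (SE 0.17, adjusted p = 0.00390). TGFB1 itself was at 0.35 (adjusted p = 0.171) and ACTA2, smooth muscle actin, at 0.85 (adjusted p = 0.382). The progenitor genes PDGFRA (0.72, adjusted p = 0.135) and DPP4 (0.91, adjusted p = 0.303; 0.46 without the RCA library of pair 6) did not pass; PDGFRA did without the RCA library of pair 1 (adjusted p = 0.0160). Of 27 WNT and BMP genes, 3 rose and 2 fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.144). ID3, a BMP target, rose by 1.06 and DKK2, a WNT antagonist gene, fell by 1.66.

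**Figure D3:**
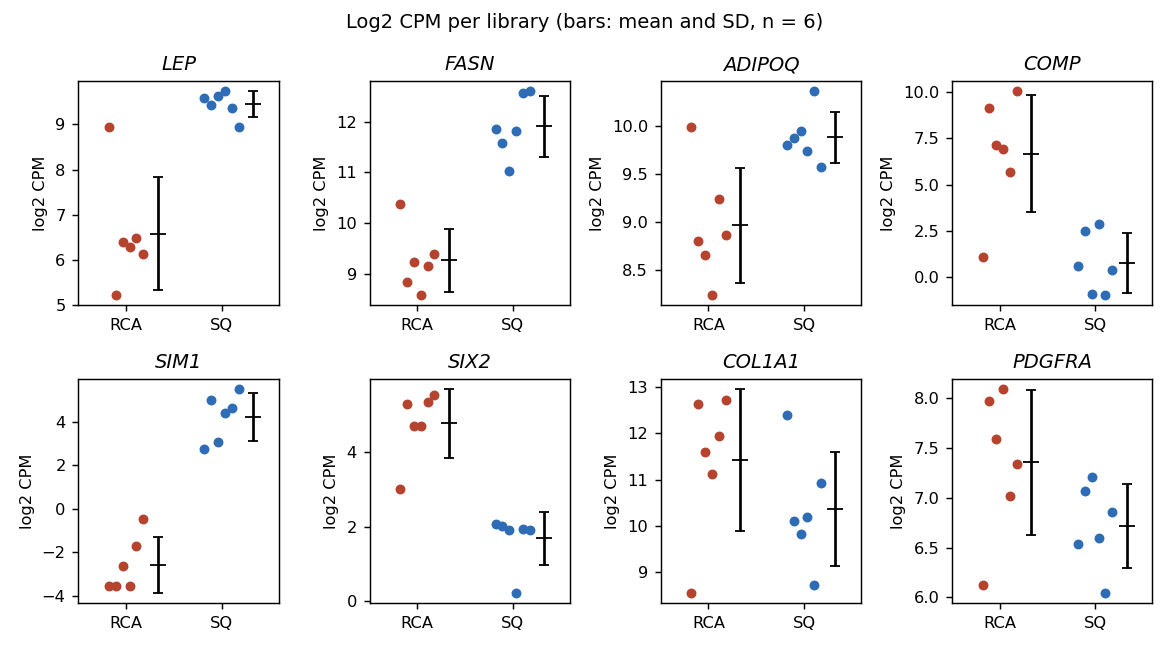
Log2 CPM of 8 genes in each library, with the group mean and SD (n = 6) beside the points. SIM1, SIX2 and FASN do not overlap between the groups, while COL1A1 and PDGFRA do. ADIPOQ, COMP and LEP overlap only through the RCA library of pair 1.

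Genes that mark body position differed between the sites. Of 43 measured HOX and other positional genes, 4 rose and 11 fell (7 and 13 when adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.0489, adjusted p = 0.518 with an estimated correlation). The list's call was lost in 5 of the 12 fits that left out 1 library: without the RCA library of pair 1 (adjusted p = 0.107) or pair 4 (0.0592), or the SQ library of pair 1 (0.0586), pair 3 (0.0501) or pair 4 (0.0951). It was also lost in limma voom with sample weights (0.199) and with the adipocyte covariate (0.283). The median was -0.14, -0.15, -0.16 and -0.060 without the SQ library of pair 2, 3, 5 or 6. SIM1 and IRX1 had the smallest p. IRX1 (chromosome 5, 3596054 to 3601403) was at 0.961 ± 0.431 CPM in RCA and 13.1 ± 5.35 CPM in SQ, a log2 fold change of -3.76 (SE 0.36, adjusted p = 0.000254, edgeR).

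Among immune and vessel lists, mast cell genes were lower. Of 12 members, 3 fell and none rose (6 fell when adjusted over the list alone), with a median of -0.97 (camera adjusted p = 1.46e-05, adjusted p = 0.518 with an estimated correlation). The protease genes CMA1 and CTSG fell by 1.73 and 1.78, and lost their calls in 3 and 4 of the 12 fits without 1 library (adjusted p up to 0.0580 and 0.0586). Of 21 macrophage genes, 1 rose and none fell, also when adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0131, adjusted p = 0.743 with an estimated correlation). The list's call was lost without the RCA or the SQ library of pair 4 (adjusted p = 0.0738 and 0.121), with a median of 0.15 without the SQ library. The scavenger receptor gene STAB1 rose by 0.72, a call lost in 8 of 12 fits without 1 library (adjusted p up to 0.0659) and with the pair as a block (0.0704), and CD163 was at 0.78 (adjusted p = 0.0811; 0.0336 in DESeq2). CD68 failed the count filter with 76 counts in all RCA and 35 in all SQ libraries, which does not show low expression, since the counting of reads shared by overlapping genes is not known. Of 10 lymphatic endothelium genes, 1 rose and none fell, also when adjusted over the list alone, with a median of 1.42 (camera adjusted p = 0.0312, adjusted p = 0.743 with an estimated correlation). This call was lost in 6 of 12 fits without 1 library (adjusted p up to 0.121 at a median of 0.78, without the RCA library of pair 2), with the filter of 1 CPM (0.0541) and in limma voom with sample weights (0.0555). PDPN, podoplanin, which synovial lining cells also express, rose by 3.18 and lost its call in 7 of those fits (adjusted p up to 0.0671) and with the pair as a block (0.128), and CCL21, a lymphatic chemokine gene, was at 3.10 (SE 1.22, adjusted p = 0.128; 0.0423 in DESeq2), and at 1.9998 without the RCA library of pair 2. IL6 was at 0.64 (SE 0.61, adjusted p = 0.544), and at 1.15 without the SQ library of pair 1.

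In the epidermis and sweat gland list, 1 of 9 members rose and 2 fell (2 and 2 when adjusted over the list alone; camera adjusted p = 0.921). KRT5, a basal keratin gene, fell by 2.08 and KRT18, a keratin of simple epithelia, rose by 1.38. No member of the skeletal muscle list passed over all genes (11 of 14 rose when adjusted over the list alone; camera adjusted p = 0.0598). Its mean was 7.65 log2 CPM in the RCA library of pair 6, where all 14 members were highest, and at most 2.14 in the other RCA libraries. The other 15 lists did not pass camera in the comparison without a block and had at most 2 members past the threshold. With the pair as a block, the immediate early and heat shock (adjusted p = 0.0264), hypoxia response (0.0366) and red blood cell (0.0283) lists passed. With the adipocyte covariate, the medians of the TGF-beta, macrophage and lymphatic lists turned below 0 and the nuclear mitochondrial median was -0.050, all without a call; that the mature adipocyte list held no call there is fixed by the covariate, which is its own mean. The lists that passed fry, which tests whether a list's genes move on balance 1 way, were 6, all lower in RCA: 5 of the 10 that passed camera, and the hypoxia response (adjusted p = 0.0106).

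**Figure D4:**
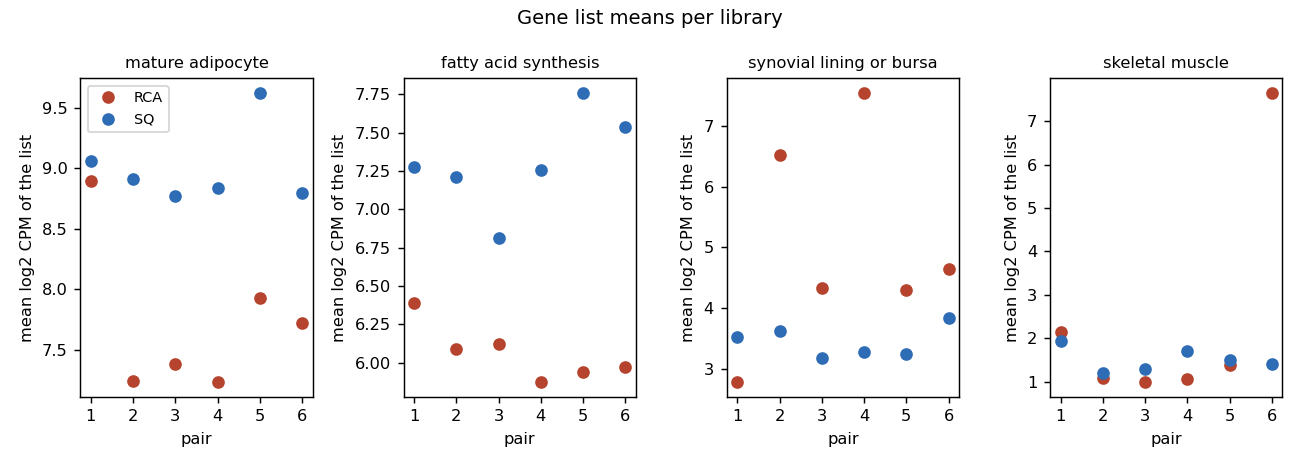
Mean log2 CPM of the members of 4 gene lists in each library, by pair, with RCA in red and SQ in blue. The RCA library of pair 1 lies at 8.90 in the mature adipocyte list, and that of pair 6 at 7.65 in the skeletal muscle list.

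None of the 5 measures of library composition passed the threshold after adjustment, which with 6 libraries per group does not show equal composition. RCA libraries held 37070 ± 762 detected genes and SQ libraries 36121 ± 900 (SD, n = 6; exact two-sided permutation p = 0.0714, adjusted p = 0.357), with more in RCA in 6 of 6 pairs. The 13 mitochondrially encoded genes took 4.58 ± 1.10% of counts in RCA and 5.24 ± 1.20% in SQ (n = 6; exact permutation p = 0.335, adjusted p = 0.617). On the first principal component of log2 CPM, which held 30.8% of the variance, the RCA library of pair 1 lay at -40.4, among the SQ libraries (-72.8 to -18.8), and the other RCA libraries lay from 29.5 to 82.4.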

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

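All tests weighed here were chosen after the results they concern had been seen. In 148 groups of 6 values, 14 had a library far from the other 5 by Dixon's criterion, where chance gives about 1 in 20 groups, or 7.4.

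The RCA library of pair 1 was far from the other RCA libraries in SIX2 (lowest, 3.02 log2 CPM), PMEPA1 (highest, 8.28) and LEP (highest, 8.95). The RCA library of pair 6 was far in DEFB132 (highest, -0.25 log2 CPM), in the skeletal muscle list (highest mean, 7.65) and in depth (highest, 32086480 counts). The SQ library of pair 5 was far from the other SQ libraries in SHISAL1 (lowest, -3.58 log2 CPM), NDUFB5 (highest, 5.27), and the means of the mature adipocyte list (highest, 9.62), the fibrillar collagen and matrix list (lowest, 7.32) and the nuclear mitochondrial respiratory chain list (highest, 5.83). The SQ library of pair 4 was far in SIM2 (lowest, -1.30 log2 CPM) and SIX2 (lowest, 0.23), and the SQ library of pair 1 in GALNT13 (highest, 7.62).

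The RCA library of pair 1 lay among the SQ libraries on the first principal component. A candidate explanation is more fat cells in that biopsy, and its mature adipocyte mean of 8.90 log2 CPM, above every other RCA library and inside the SQ range, is what that needs. A subcutaneous library under an RCA label was tested on the 18 positional genes called without this library, on a scale with 0 at the SQ mean and 1 at the mean of the other RCA libraries. Their median position was 0.71 (quartiles 0.55 and 0.98, 14 of 18 above 0.5). The 6 SQ libraries, each left out when its genes were called and its scale was set, had medians from -0.22 to 0.33. Those of the other RCA libraries were 0.87 to 1.17. By the medians, this argues against a wholly subcutaneous library, but the quartile ranges overlapped. The upper quartiles of the SQ libraries of pairs 1 and 6 were 0.58 and 0.69, above the lower quartile of 0.55. This comparison replaced bounds of 0.25 and 0.75, under which 0.71 was undecided, and an earlier one of 0.5, under which it was not; over all 4444 genes called without the library the median was 0.19, and a biopsy with some subcutaneous fat in it was not tested.

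The genes lower in RCA may reflect a lower share of fat cells in those biopsies. With the mature adipocyte mean as a covariate, the median of the 1516 lower genes went from -0.68 (quartiles -1.09 and -0.47) to -0.36 (-0.65 and -0.20), that of the fatty acid synthesis list from -1.04 (-1.66 and -0.61) to -0.85 (-1.30 and -0.18), and that of the 11 lower positional genes from -1.23 (-1.46 and -0.86) to -1.45 (-2.003 and -0.57). The covariate correlates with the site at -0.81, and at -0.93 without the RCA library of pair 1, where the medians were -0.38, -0.58 and -0.84 and 0 genes passed in edgeR (1869 at an unadjusted p below 0.05). The fatty acid synthesis list kept its camera call in both fits (adjusted p = 1.43e-06 and 0.000216), but single calls rest on that 1 library and the list's mean fell by about as much as the adipocyte mean (difference 0.02, exact permutation p = 0.937), so the share of fat cells and the site cannot be told apart for these genes. In the RCA library of pair 1, whose adipocyte mean was inside the SQ range, the fatty acid synthesis mean was 6.39 log2 CPM. That lay below every SQ library (6.81 to 7.76) and above the other RCA libraries (5.87 to 6.12), but it is 1 library. A difference between the fat of the 2 sites themselves stays open and untested.

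The synovial lining genes may come from lining tissue in some RCA biopsies. Their mean pairwise correlation was 0.49 over the 6 RCA libraries and -0.0096 over the SQ libraries. Other cell type lists ran from 0.076 (stromal or progenitor) to 0.56 (lymphatic) in RCA. Mast cell (0.52) and lymphatic genes lay above the synovial value, so this stays open. A lower share of fat cells alone would raise the genes of other cell types alike. The changes of 10 other cell type lists did not spread beyond chance (exact permutation p = 0.0974, and 0.177 without mast cells). This does not show that they changed alike. Mast cell genes fell by 1.17 (exact permutation p = 0.00649), against such a rise, but they are 1 list of 10. The test leaves out the synovial list itself, so it cannot decide between fewer fat cells and lining tissue. The spread with the synovial list included (exact permutation p = 0.0238) restates in part that list's own rise; the changes ran from -1.17 for mast cells to 1.58 for synovial lining. Of 2 single contrasts, synovial lining rose more than mast cells (exact permutation p = 0.00216, the smallest the design allows). These lists lie at the ends of that range, and the p makes no allowance for that choice, so it decides nothing here. Against blood endothelium the difference of 1.43 did not pass (exact permutation p = 0.0952). Expression of these genes by the subacromial fat itself was not tested.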

How the results depend on the processing

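The covariate for adipocyte genes and the omissions of the unmatched pair and of pairs 1 and 6 were chosen after seeing the data; the other settings were planned. The bounds for the test of other splits were written after it had been run. Of 100 library splits (6 and 6), the real one called 2401 genes and the highest other 1. The least possible share is 1 of 100, other splits mixed the sites and pairs were ignored, so chance is not excluded.

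The numbers of the pairs were not taken to pair the libraries. Deviations from the group mean correlated at 0.15 on average within pairs (0.09 to 0.23, over 0.1 in 5 of 6) and at -0.03 between unmatched libraries; over the 2000 most variable genes the mean was 0.24 (0.12 to 0.34, over 0.1 in 6 of 6). Each library correlated best with its own number in 5 of 6 pairs, and in 6 of 6 over those 2000 genes, a hint from the data and not from the labels. With the pair as a block, 2022 genes passed, 1620 of them shared with the main result, and 13 lists, the 3 added being immediate early and heat shock, hypoxia response and red blood cell; leaving out both libraries of a pair gave 371 to 3970 genes. The block ended the calls of CHI3L2, PLA2G2A, STAB1 and PDPN among the 54 named genes, and ADIPOQ passed under it.

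The 2401 genes became 1528 without a count filter, 4101 with voom and sample weights, 3817 with DESeq2, 868 at an absolute log2 fold change of at least 1, 4255 at an adjusted p below 0.1, 1218 with the muscle covariate and the block, 846 (815 shared) without the unmatched pair, 4202 without the RCA libraries of pairs 1 and 6, and 53 (29 shared) with the adipocyte covariate. Leaving out 1 library gave 1203 to 4505; counts changed by over 1.5 times without the RCA library of pair 1 (4505), 2 (1203), 3 (1332) or 4 (1313) or the SQ library of pair 2 (1350), 3 (1421) or 5 (1471). The threshold, the filter and the number of libraries set part of these counts by construction; otherwise the cause was not tested. The 10 lists became 16 without a filter, 1 with an estimated correlation and 6 with fry. Of 44 named genes that passed, 33 passed in all 12 fits without 1 library.

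With the adipocyte covariate, ALDOC, IRX1 and NRCAM kept their calls, 38 other named genes lost theirs without a change of direction, and directions reversed, with no call unless given, in CHI3L2 (-1.18), PDPN (-0.95), CCL21 (-1.44), CRTAC1 (-1.09), ADIPOQ (0.16), COL1A1 (-1.34), COL3A1 (-0.85), TGFB1 (-0.053), ACTA2 (-0.60), PDGFRA (-0.80) and DPP4 (-0.87). Camera's direction reversed in these lists, with the medians given; those of the mature adipocyte list (the covariate itself) and the nuclear mitochondrial list stayed below 0: mature adipocyte -0.038, thermogenic 0.25, collagen and matrix -0.69 (called lower, adjusted p = 2.97e-08), TGF-beta -0.12, stromal or progenitor -0.11, macrophage -0.29, acute inflammation -0.045, lymphatic -1.20, tendon and cartilage -0.27, synovial lining -0.70, nuclear mitochondrial -0.050 and mitochondrially encoded 0.14. That fit without the RCA library of pair 1 called 0 genes in edgeR (53 with it; 1869 without it at an unadjusted p below 0.05), so single calls in it rest on 1 library that separates the covariate from the site. Without that library the collagen and matrix list was still lower (-0.45, camera adjusted p = 0.0298), and the synovial (-0.67) and TGF-beta (-0.24) lists held no call. Acute inflammation (0.84, 0.0175) and others were newly called. With the covariate and all libraries, calls were gained for peripheral nerve (-1.44, adjusted p = 0.000327), antigen presentation (-0.87, 0.000800), interferon (0.90, 0.00190), skeletal muscle (3.25, 0.0211) and blood endothelium (0.36, 0.0387), and the mast cell median was -2.31.

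Camera's direction also reversed in lists without a call, given with their medians (the neutrophil median was 0.15 before and never changed sign here, nor did interferon without the unmatched pair): epidermis with the block (0.094), the 1 CPM filter (0.29) and voom with weights (0.21); neutrophil with that filter (0.22), those weights (0.46), without the unmatched pair (0.16) and without pairs 1 and 6 (0.50); interferon without the unmatched pair (0.0029); and, without pairs 1 and 6, T and NK cell (0.18), B and plasma cell (0.017) and skeletal muscle (-0.14). Over the fits without 1 library, medians ran from -0.042 to 0.43 for neutrophil, -0.13 to 0.33 for T and NK cell, -0.060 to 0.43 for interferon and -0.88 to 0.055 for peripheral nerve. The cause was not tested. At 20296871 to 32086480 counts per library, UCP1 stayed below the count filter.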

Other observations

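All of the following groups were chosen after the values had been seen: 21 gene families were looked through, and each was then tested for more higher or more lower calls than among the other genes (Fisher's exact test, one-sided, 42 tests adjusted together). Complement genes were called higher more often, 6 of 24 (adjusted p = 0.00585), with 1 called lower. C6, part of the membrane attack complex, rose by 2.57 (SE 0.41, adjusted p = 0.00454, edgeR), from 20.8 ± 10.04 CPM in SQ to 124 ± 66.6 CPM in RCA (SD, n = 6), and C1R and C1S, proteases that start the classical pathway, rose by 1.28 and 0.82. C5, C4A and C4B also rose, and CD46, an inhibitor of complement on cell surfaces, fell by 0.49. C4A and C4B are near-identical, and counted as 1 gene they would leave 5.

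Small leucine-rich proteoglycans, which bind collagen fibrils, were called higher in 4 of 10 (adjusted p = 0.00585). ASPN rose by 3.38, BGN by 2.997, OGN by 1.22 and PODN by 1.01. Of the 37 collagen genes tested, 1 rose and 1 fell. Metallothionein 1 genes rose in 3 of 8 (adjusted p = 0.0153), with near-identical copies whose separate values are uncertain, and genes with ion channel names rose in 12 of 128 and fell in 6 (adjusted p = 0.0153 for the higher ones), some of them antisense or other non-coding genes. Among homeobox families, IRX1, IRX2 and IRX5 fell of 5 IRX genes (adjusted p = 0.0153) and both DLX genes tested, DLX3 and DLX4, which are neighbours on chromosome 17, rose (adjusted p = 0.0153). The family of SIX2 (2 of 5 higher, adjusted p = 0.0615) and the AKR1C family (3 of 8 lower, adjusted p = 0.0599, but 0.0348 with upper-quartile factors) did not pass, nor did the other 13 families. The families that passed did so with RLE and upper-quartile factors too. Of their members, only IRX1 was among the 29 calls kept with the adipocyte covariate. Whether these family changes follow the share of fat cells was not tested. Genes of a family are not independent of each other, and these p-values treat them as if they were.

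In the RCA library of pair 6, all 14 measured skeletal muscle genes were above every other library. ACTA1 stood at 1475 CPM there and at most 2.69 CPM elsewhere, and TTN at 9588 against at most 364 CPM.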
